A study of Homo sapiens with 24 samples.

How the data were processed

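RNA from 24 slices of a reconstructed human skin tissue, EPI-200, was measured on 1-colour Agilent arrays, 1 array per slice. The labels give 8 groups of dose and distance with 3 replicates each, and call the 3 repeats biological. The 4 slices of a tissue lay on 1 slide in fixed array positions, so the 6 slides held 6 tissues of 1 dose each, and distance and array position coincided within a dose. Control and irradiated slides of the same replicate number were scanned on the same day, over 3 scan days.

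Per the file headers, the scanner files were made with Feature Extraction 9.1.3.1 and hold intensity values, background-subtracted and spatially detrended within each array, with no scaling between arrays. The deposited series matrix holds log2 values. Set against the scanner files, from 99% to 99.7% of its probes on each array lay within 0.01 of the log2 intensity plus 1 constant per array. That constant ranged from -0.341 to 4.68, and the array medians of the matrix ranged from 6.78 to 9.14. How the authors chose the constant, and which filter left spots empty, stays unknown. No pair of arrays was identical (0 pairs).

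Signals of the same probe were averaged, outlier spots left out. Each array was divided by the 75th percentile of its 41000 non-control probes, values under 0.05 of that percentile were set to it (-4.32 on the log2 scale), and log2 was taken. Probes well above background on all 3 arrays of at least 1 group were kept (22565), and each gene was represented by the probe with the highest mean, which left 17421 genes. Of the probes, 23680 were matched to a current gene symbol by accession, 2802 by symbol and 1125 by an older symbol, while 13393 kept the name in the files. XIST and Y-linked probes (75) were left out. Where every array of 1 group of a slice lay below the level called well above background, a fold is given as a lower bound against the dimmest signal above background, or the probe's own where that was higher.

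Differences were tested in R 4.3.3 with limma 3.58.1 (files read with version 1.17.8 of data.table). The model held 8 group means with the slide as a random block (consensus correlation 0.277), and genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The mean of the 3 outer slices, and that mean minus the 0-250 µm slice, were tested on 1 value per tissue, 3 irradiated against 3 control. Distance within a dose and the dose by distance interaction were tested with F tests in the model of all arrays. For single genes, the p-values of the outer results on 1 value per tissue measure the spread between tissues. Those of distance and the interaction measure that between slices within tissues. Those of dose in 1 slice, or of the outer slices over all arrays, measure both. Errors given with a log2 difference are standard errors of the model unless named SD. The number of arrays limits the precision.

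The design, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The 28 gene lists were p53 targets, DNA repair, cell cycle and mitosis, DNA replication, inflammatory cytokines and chemokines, NF-kappaB feedback and prostaglandin genes, matrix metalloproteinases and inhibitors, interferon response, basal keratinocyte, suprabasal and cornified envelope, lipid barrier and ceramide genes, sterol and fatty acid synthesis, NRF2 oxidative stress, metallothioneins, heat shock and unfolded protein, hypoxia and glycolysis, EGFR ligands and immediate early genes, TGF-beta and wound matrix, antimicrobial and S100, gap junction and connexin, apoptosis regulators, oxidative phosphorylation, ribosomal proteins and replication-dependent histones, with markers of melanocytes, fibroblasts, immune and endothelial cells, and sweat, sebaceous and hair follicle cells. Lists were tested with cameraPR at a preset inter-gene correlation of 0.01, again with a correlation estimated from the residuals, and with fry, each adjusted over the lists. The cameraPR p-values set the genes of a list against the other genes, so they measure the spread between genes, not between tissues. Values of fry are not given. Named genes were, per dose comparison, the 12 largest increases and 12 largest decreases among called genes with a symbol whose 3 irradiated values all lay on the same side of the 3 control values, so that these lie in the same direction in every pair by construction. For distance the limit was 6 each way. Places left were filled from the lists by lowest p, and 13 genes were always given, of which MKI67 and CXCL8 did not pass the background filter and were not tested. List members named beyond these were those with the lowest p of their list.

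Whether replicate numbers pair the samples was decided by a criterion set before the data were examined, a correlation above 0.1 in every pair after group means were removed. It was computed after counts of called genes with and without that block had been seen. Control and irradiated arrays of the same number correlated at 0.165 to 0.694 in all 12 pairs, so the numbers were treated as pairing the samples. Those of different numbers correlated at 0.0894 or less. The deviations of a group sum to 0, which pushes these down where the former are positive, so the contrast adds little. Replicate number and scan day coincide, so a shared scan day cannot be told apart from a shared experiment. The value with replicate number as a block is given where it moved a result.

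Alternatives covered quantile normalization, median scaling, normexp background correction (offset 50), the series matrix values (17403 genes), no background filter, a filter on all 24 arrays, every probe, array weights, no slide block, a fixed slide block, the 6 arrays of a distance alone, the replicate block, an estimated inter-gene correlation, an unadjusted threshold of 0.001, and leaving out each replicate number and each tissue. The following were chosen after seeing the data: a floor of 0.1, leaving out the 2 arrays of low quality (17783 genes; consensus correlation 0.729), leaving these out with the replicate block (consensus correlation 0.112), and the outer slices tested in that model over all remaining arrays. The combination of these last choices was picked after 4 models had been looked at. The normexp offset of 50 was added before scaling, where the median signal of the arrays was 1.12 to 62.2. It shrinks log2 differences of dim genes, and more so on dim arrays. Fewer calls with normexp thus do not speak of background correction alone.

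The steps were tested on simulated data, with the spread of each of 17421 genes and the slide correlation of the arrays. For dose at 0-250 µm the model recovered 8% of genes changed 2-fold and 57% of those changed 4-fold, with 4 false calls of 69. For the mean of the outer slices it recovered 1% and 40%, with 1 false call of 42, against 28% and 77%, with 13 false calls of 118, when the outer slices were tested over all arrays. For distance in control tissue it recovered 13% and 62%, with 4 false calls of 79. With no true difference, outer slices minus 0-250 µm and the interaction each gave 0 calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.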

Results

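Gene expression was measured in 24 slices of EPI-200, a reconstructed human skin tissue grown in culture. Across 3 tissues a strip 25 µm wide had received 0.5 Gy of alpha particles (helium ions of 9 MeV), and 3 control tissues had received 0 Gy. At 16 h each tissue was divided into slices at 0-250, 250-500, 500-750 and 750-1000 µm from the irradiated plane, and 0.1 µg of RNA per slice was put on a 1-colour array. Slices beyond 250 µm thus came from tissue outside the strip, and the question the series poses is how genes respond there. The strip filled only a small part of the 0-250 µm slice, so values of that slice mix irradiated tissue with tissue beside it. Each of the 8 groups held 3 arrays.

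On 22 arrays the 75th percentile of the signal ranged from 110 to 423 intensity units, and 49.5% to 62.5% of probes were well above background. The correlation of each with the mean of these arrays was 0.968 to 0.994. The other 2 arrays stood apart. The array of irradiated tissue at 250-500 µm, replicate 2, had a 75th percentile of 10.8, 16.8% of probes well above background and a correlation of 0.722. The array of control tissue at 500-750 µm, replicate 1, had a 75th percentile of 285 and a correlation of 0.869. Both are in all values below unless their absence is stated, a choice made after their quality had been seen.

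In the slice that held the strip (0-250 µm), the xenobiotic-metabolizing oxidase CYP1B1 rose 20.4-fold, from a log2 signal of -3.23 ± 0.52 in control tissue to 1.12 ± 0.33 in irradiated tissue (SD, n = 3 each). The acute-phase protein gene SAA1 rose by 2.49 ± 0.39 (log2; adjusted p = 0.0134) and SOD2, the mitochondrial superoxide dismutase, by 2.05 ± 0.36 (0.038). The stromelysin gene MMP10 fell by 3.01 ± 0.54, the retinaldehyde dehydrogenase ALDH1A3 by 2.13 ± 0.38, keratin KRT19 by 1.94 ± 0.29 and MAL by 1.88 ± 0.24. Also lower, the interstitial collagenase MMP1 fell by 1.83 ± 0.24, galectin LGALS1 by 1.35 ± 0.22 and ZBED2 by 1.26 ± 0.20. These 10 genes, 3 higher and 7 lower, lay in the same direction in 3 of 3 same-day pairs, as the rule by which they were named requires. Adjusted p in limma was 1.23e-07 for CYP1B1 (difference 4.35 ± 0.30) and at most 0.038 for the others.

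Of 15 measured matrix metalloproteinases and inhibitors, MMP1 and MMP10 fell over all genes, and 5 fell adjusted over the list alone, with MMP9 at -1.57, MMP3 at least 2.7-fold lower and PLAU at -1.0. The list moved down with a median of -0.21 (adjusted p = 5.55e-15; adjusted p = 4.65e-17 with an estimated correlation), 9 of its genes lower and 6 higher. Among 15 NF-kappaB feedback and prostaglandin genes, SOD2 rose over all genes, and SOD2 and TNFAIP2 (0.73) adjusted over the list alone. That list moved up with a median of 0.15 (adjusted p = 0.00138; adjusted p = 0.0139 with an estimated correlation; 0.124 with normexp), 10 of its genes higher, and PTGS2 stood at -0.44 ± 0.72. Of 20 basal keratinocyte genes, KRT19 fell over all genes, and adjusted over the list alone LAMA3 (-1.15) was among those that fell. The median was -0.23 with 14 genes lower (adjusted p = 3.45e-07; adjusted p = 0.203 with an estimated correlation). The cysteine-rich, metal-binding metallothioneins moved up, 7 of 10 higher, with a median of 0.40 (adjusted p = 2.63e-05; adjusted p = 0.085 with an estimated correlation). Adjusted over the list alone, 2 of them rose, MT1G (0.88) and MT2A (1.34).

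EGFR ligands and immediate early genes moved down, 20 of 26 lower, with a median of -0.23 (adjusted p = 0.00139; adjusted p = 0.085 with an estimated correlation), while none passed adjusted over the list alone (0 of 26; DUSP6 at -0.74, PHLDA1 at -0.99). DNA replication genes moved up, 22 of 25 higher, median 0.20 (adjusted p = 0.00448; adjusted p = 0.63 with an estimated correlation), with MCM10 at 1.10 and RFC3 at 0.94. NRF2 oxidative stress genes moved up, 17 of 25 higher, median 0.12 (adjusted p = 0.0081; adjusted p = 0.681 with an estimated correlation; 0.0604 with normexp), with AKR1C1 at 0.93 and GPX2 at 0.46. Sterol and fatty acid synthesis genes moved down, 21 of 28 lower, median -0.19 (adjusted p = 0.0176; adjusted p = 0.681 with an estimated correlation). The 28 measured p53 targets held 0 called genes in limma and a median of -0.07 (adjusted p = 0.964), with CDKN1A at 0.10 ± 0.35, MDM2 at -0.10 ± 0.58 and GDF15 at -0.32 ± 0.24. Further genes that did not pass were IL1B (-1.33 ± 0.53), FOS (-0.57 ± 0.71), MX1 (-1.20), IFI27 (-0.71) and DEFB4A (0.89). So were CAMP (1.15), S100A7A (1.48), CCL27 (0.88), KRT1 (0.24) and KRT14 (-0.03).

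With median scaling 5 genes passed, 3 higher and 2 lower, with normexp background correction 0 (266 main genes had an unadjusted p under 0.05), and without the 2 arrays 38, 12 higher and 26 lower. Leaving out 1 tissue gave from 2 genes (without control tissue 3) to 31 (without irradiated tissue 2), with 3 and 4 without irradiated tissues 1 and 3.

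**Figure D1:**
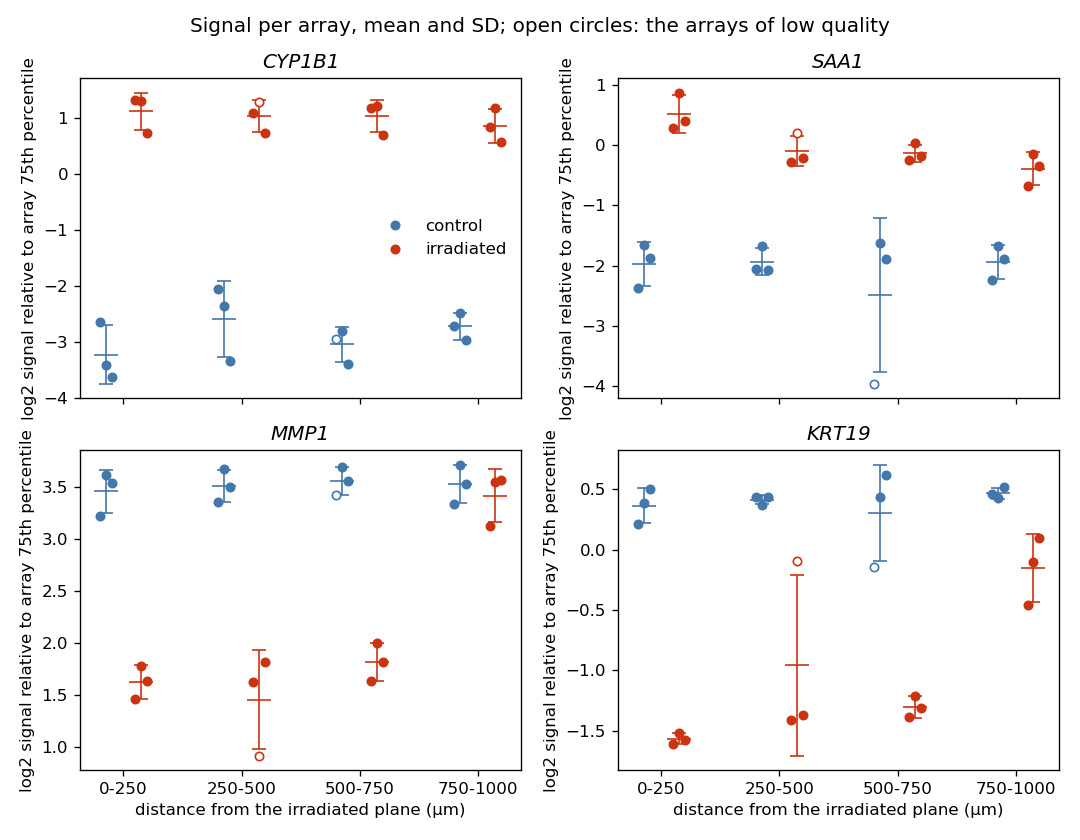
Log2 signal of CYP1B1, SAA1, MMP1 and KRT19 on each array (vertical axis, relative to the 75th percentile of the array) by distance from the irradiated plane in µm (horizontal axis), control in blue and irradiated in red, with the mean and SD of 3 arrays and open circles for the 2 arrays of low quality. At 0-250 µm CYP1B1 averaged -3.23 in control and 1.12 in irradiated tissue.

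At 250-500 µm, the slice next to the strip, CYP1B1 again rose, by 3.63 ± 0.30 (adjusted p = 2.9e-06), together with the complement factor CFB, at least 21.7-fold (adjusted p = 0.0213; at least 9.29-fold without the 2 arrays), and the acute-phase gene SAA2 (2.30 ± 0.40). MMP1 fell by 2.06 ± 0.24 (adjusted p = 0.000448), the interferon-induced GTPase MX1 by 1.94 ± 0.31 (1 of 3 irradiated arrays above background, so the floor limits the size), PHLDA1 by 1.93 ± 0.34 and ZBED2 by 1.34 ± 0.20. These were among 8 genes, 3 higher and 5 lower, that kept their direction in 3 of 3 same-day pairs, with adjusted p of at most 0.0359 in limma. The 4 probes of PHLDA1 ran from -1.93 to 0.25. The median of all genes was -0.27 in this slice, -0.04 with median scaling and -0.20 with quantile normalization. Relative to the all-gene median CYP1B1 stood at 3.90, SAA2 at 2.57, MMP1 at -1.79, MX1 at -1.67, PHLDA1 at -1.66 and ZBED2 at -1.07.

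Relative to that median, the matrix metalloproteinase list stood at -0.57 with 12 of 15 genes lower (adjusted p = 0.0052; adjusted p = 0.0064 with an estimated correlation), and 5 fell adjusted over the list alone, among them PLAU (-1.19), MMP9 (-0.97) and MMP3 (-0.90). EGFR ligands and immediate early genes stood at -0.47 (adjusted p = 0.000141; adjusted p = 0.03 with an estimated correlation), 22 of 26 lower, and 8 fell adjusted over the list alone, among them DUSP6 (-0.83), MYC (-0.83) and AREG (-0.65). Basal keratinocyte genes stood at -0.54, 18 of 20 lower (adjusted p = 2.59e-05; adjusted p = 0.458 with an estimated correlation), and 4 fell adjusted over the list alone, among them LAMA3 (-1.29) and KRT19 (-1.11). Sterol and fatty acid synthesis genes stood at -0.39 (adjusted p = 0.0128; adjusted p = 0.735 with an estimated correlation; 0.0598 with median scaling and 0.0543 with quantile normalization), 26 of 28 lower. Oxidative phosphorylation genes stood at -0.14 (adjusted p = 0.021; adjusted p = 0.735 with an estimated correlation; 0.204 with median scaling and 0.117 with quantile normalization), 24 of 26 lower. The numbers of lower genes, and the tests of single genes adjusted over the list alone, are against 0, not against that median. Not taken relative to that median, genes that did not pass included IFI27 (-1.19), IL1B (-2.08), PTGS2 (-2.51), INHBA (-1.96) and FOS (-2.20). Others were MMP10 (-1.23), CXCL1 (-1.12), ID1 (-0.78), TNFAIP2 (0.73), DEFB4A (0.83), MT1G (0.74), CDKN1A (-0.33), MDM2 (-0.41), GDF15 (-0.08), KRT1 (0.74) and KRT14 (-0.58). Several values rested on the array of low quality, and without the 2 arrays MMP9 stood at -1.83, PTGS2 at -1.08, FOS at -0.92, IL1B at -1.22, INHBA at -1.31, MMP10 at -2.0, KRT1 at -0.03, KRT14 at 0.04, CDKN1A at 0.10, MDM2 at 0.04 and GDF15 at -0.21.

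The replicate block gave 22 genes, 7 higher and 15 lower, median scaling 9, 6 higher and 3 lower, and leaving out the 2 arrays 34, 10 higher and 24 lower, with an all-gene median of -0.04. Without irradiated tissue 2, whose array in this slice was of low quality, 19 genes passed, and leaving out the others gave 4 (control 2), 4 (control 3), 5 (irradiated 1) or 3 (irradiated 3).

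At 500-750 µm CYP1B1 rose by 4.09 ± 0.30 (adjusted p = 3.66e-07), SAA1 by 2.36 ± 0.39 (1.75 without the 2 arrays) and CYP1A1, a related oxidase controlled by the aryl hydrocarbon receptor, by 2.03 ± 0.33 (0.0138). The activin inhibitor FST fell by 1.98 ± 0.32 (1 of 3 irradiated arrays above background, so the floor limits the size), MAL by 1.79 ± 0.24, MMP1 by 1.74 ± 0.24, KRT19 by 1.61 ± 0.29, LGALS1 by 1.51 ± 0.22, IFI27 by 1.44 ± 0.22 and ZBED2 by 1.39 ± 0.20. The 10 genes, 3 higher and 7 lower, lay in the same direction in 3 of 3 same-day pairs with adjusted p of at most 0.0418 in limma. A dimmer probe of MMP1 stood at 0.28 here, -0.13 at 0-250 µm and -0.46 at 250-500 µm, so the fall of MMP1 rests on 1 of 2 probes. Of the 7 lower genes 5 were the same as at 0-250 µm, and of the 3 higher genes 2 were.

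The matrix metalloproteinase list moved down with a median of -0.25, 11 of 15 genes lower (adjusted p = 3.64e-06; adjusted p = 4.88e-07 with an estimated correlation; 0.0514 with normexp), and 5 fell adjusted over the list alone, among them MMP9 (-1.80) and MMP10 (-2.24). EGFR ligands and immediate early genes moved down, 19 of 26 lower, median -0.43 (adjusted p = 1.24e-05; adjusted p = 0.00958 with an estimated correlation; 0.391 with normexp), and DUSP6 (-1.25), PHLDA1 (-1.52), MYC (-1.07) and AREG (-0.74) fell adjusted over the list alone (4 genes). Metallothioneins moved up, 8 of 10 higher, median 0.70 (adjusted p = 1.24e-05; adjusted p = 0.0897 with an estimated correlation), and MT1G (0.84) rose adjusted over the list alone (1 gene). Sterol and fatty acid synthesis genes moved down, 21 of 28 lower, median -0.20 (adjusted p = 0.00756; adjusted p = 0.816 with an estimated correlation; 0.0914 with quantile normalization and 0.404 with normexp). Genes that did not pass included MX1 (-1.27), SOD2 (1.44), CAMP (1.43) and S100A7A (at least 3.04-fold higher). Others were DEFB103B (-1.0), CXCL1 (-1.19), TNFAIP2 (0.67), PTGS2 (-1.27), IL1B (-1.75), MMP3 (-0.67), FOS (-1.29), CDKN1A (-0.26), MDM2 (-0.47), GDF15 (-0.58), KRT1 (0.03) and KRT14 (0.21). Without the 2 arrays MMP3 stood at -1.25, CDKN1A at 0.06, MDM2 at -0.14, KRT1 at -0.19 and KRT14 at -0.02.

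The replicate block gave 19 genes, 6 higher and 13 lower, leaving out the 2 arrays 34, 10 higher and 24 lower, normexp 0 (765 main genes had an unadjusted p under 0.05) and median scaling 7, 3 higher and 4 lower. Without control tissue 2 or irradiated tissue 2 the count was 30 or 23, and without control tissue 3, irradiated tissue 1 or irradiated tissue 3 it was 1 each.

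At 750-1000 µm, the slice farthest from the strip, CYP1B1 was the only gene to pass (3.59 ± 0.30, adjusted p = 3.5e-06 in limma, higher in 3 of 3 pairs). Of 19 measured cell cycle and mitosis genes, 18 were higher, with a median of 0.61 (adjusted p = 2.87e-26; adjusted p = 1.43e-06 with an estimated correlation), and 4 rose adjusted over the list alone, BIRC5 (0.85), the anaphase activator CDC20 (0.66), the mitotic kinase PLK1 (0.93) and DLGAP5 (1.14). Of 26 EGFR ligands and immediate early genes, 25 were lower, with a median of -0.37 (adjusted p = 5.19e-16; adjusted p = 1.32e-07 with an estimated correlation), PHLDA1 at -1.15, DUSP6 at -0.80, MYC at -0.72 and AREG at -0.67. Metallothioneins moved up, 9 of 10 higher, median 0.43 (adjusted p = 3.82e-08; adjusted p = 0.0153 with an estimated correlation; 0.863 with normexp), with MT1G (0.70) rising adjusted over the list alone (1 gene). MMP1, lower in the nearer slices, stood at -0.11 here.

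The matrix metalloproteinase list had a median of -0.11, with 10 of 15 genes lower and MMP3 at -1.18 (adjusted p = 0.0294; adjusted p = 0.0392 with an estimated correlation; 0.0619 with quantile normalization, 0.325 with normexp and 0.142 with the series matrix). DNA replication genes moved up, 19 of 25 higher, median 0.26 (adjusted p = 0.000178; adjusted p = 0.228 with an estimated correlation), with TK1 at 0.59. DNA repair genes moved up, 20 of 29 higher, median 0.11 (adjusted p = 0.0135; adjusted p = 0.676 with an estimated correlation; 0.052 with normexp), with FANCA at 1.26. The antimicrobial and S100 list moved up, 11 of 18 higher, median 0.10 (adjusted p = 0.000312; adjusted p = 0.135 with an estimated correlation), but its median was -0.24 with normexp. It held S100A7A at 1.14, DEFB4A at 0.65 and S100A12 at 0.56. Heat shock and unfolded protein genes moved down, 18 of 24 lower, median -0.08 (adjusted p = 0.0232; adjusted p = 0.28 with an estimated correlation; 0.0619 with quantile normalization and 0.0569 with the series matrix), with ATF4 at -0.55. Oxidative phosphorylation genes moved down, 24 of 26 lower, median -0.15 (adjusted p = 0.0169; adjusted p = 0.651 with an estimated correlation; 0.106 with quantile normalization and 0.0564 with the series matrix), with NDUFC1 at -0.30. Genes that did not pass included ID1 (-0.80), SOD2 (1.27), FOXM1 (0.96), SPRR2D (0.52), H1-2 (-0.40) and MT2A (0.87). Others were IER3 (-0.55), EGR1 (-0.55), PTGS2 (-1.01), IL1B (-0.61), MMP10 (-0.80), FOS (-1.05), CDKN1A (-0.02), GDF15 (-0.23), KRT1 (0.44) and KRT14 (0.27), while MDM2 was well above background on 0 of 3 irradiated arrays.

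The count was 8, 6 higher and 2 lower, without the 2 arrays, 9 without irradiated tissue 2, 5 without irradiated tissue 3 and 0 with normexp (156 main genes had an unadjusted p under 0.05). The all-gene median of -0.04 became -0.14 with median scaling, and relative to it CYP1B1 stood at 3.63, BIRC5 at 0.89 and PHLDA1 at -1.11.

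**Figure D2:**
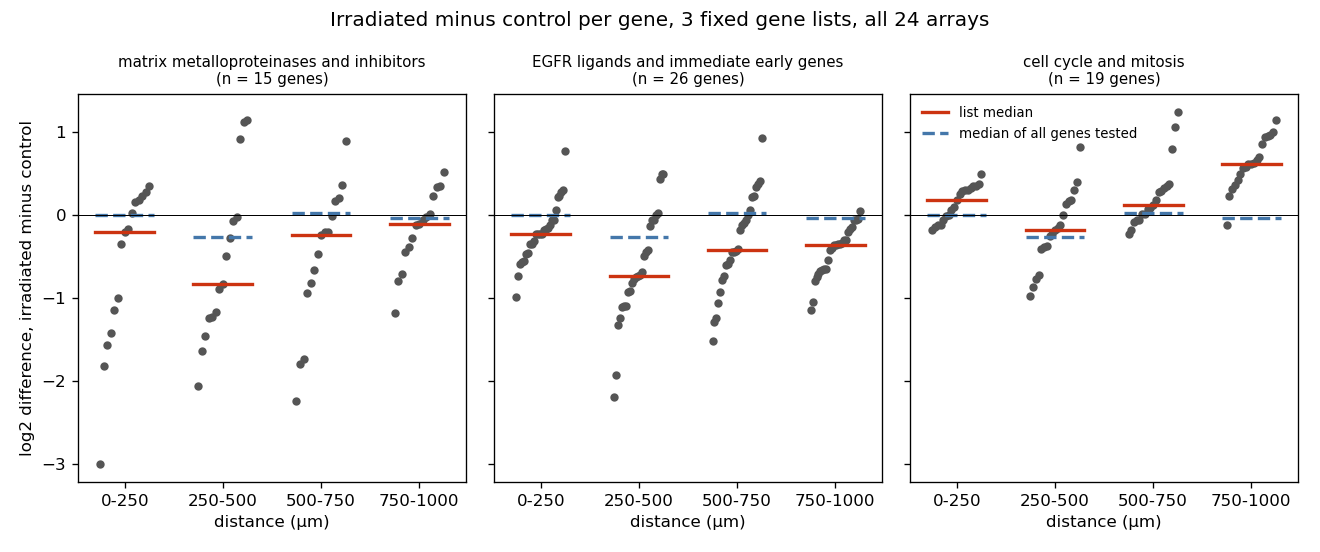
Log2 difference, irradiated minus control, of each measured member (vertical axis) of 3 fixed gene lists by distance in µm (horizontal axis), from all 24 arrays, with the median of the list in red and that of all genes as a dashed blue line. Of 19 cell cycle and mitosis genes 18 lay above 0 at 750-1000 µm, and of 26 EGFR ligands and immediate early genes 25 lay below it.

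Averaged over the 3 outer slices, which all lay beyond the strip, CYP1B1 was higher by 3.77 ± 0.29 in 3 of 3 pairs but did not pass (adjusted p = 0.0538), and CYP1A1 stood at 1.59 ± 0.27. With the replicate block CYP1B1 passed (adjusted p = 0.0109, 1 gene). In limma 0 genes passed and 622 had an unadjusted p under 0.05. The median of all genes was -0.09. EGFR ligands and immediate early genes moved down as a list, 25 of 26 lower, median -0.31 (adjusted p = 1.84e-07; adjusted p = 0.000957 with an estimated correlation), and PHLDA1 (-1.53), DUSP6 (-1.05) and MYC (-0.96) fell adjusted over the list alone (3 genes). Matrix metalloproteinases and inhibitors moved down, 10 of 15 lower, median -0.19 (adjusted p = 5.31e-05; adjusted p = 0.000144 with an estimated correlation), and 6 fell adjusted over the list alone, among them MMP1 (-1.30), MMP9 (-1.25), MMP3 (-1.0) and PLAU (-0.89).

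Cell cycle and mitosis genes moved up, 16 of 19 higher, median 0.24 (adjusted p = 1e-04; adjusted p = 0.26 with an estimated correlation), with BIRC5 at 0.45. Metallothioneins moved up, 9 of 10 higher, median 0.43 (adjusted p = 7.54e-05; adjusted p = 0.184 with an estimated correlation), with MT2A at 0.78. Sterol and fatty acid synthesis genes moved down, 27 of 28 lower, median -0.30 (adjusted p = 0.000732; adjusted p = 0.62 with an estimated correlation), with STARD4 at -0.82 and IDI1 at -0.76 (-0.39 and -0.31 without the 2 arrays). Basal keratinocyte genes moved down, 15 of 20 lower, median -0.33 (adjusted p = 0.00401; adjusted p = 0.62 with an estimated correlation), and KRT19 (-1.20) was among 2 genes that fell adjusted over the list alone. Genes that did not pass included SOD2 (1.26), PTGS2 (-1.60), IL1B (-1.48), FOS (-1.51), INHBA (-1.20), MX1 (-0.97), IFI27 (-0.93), LAMA3 (-0.87), AREG (-0.78) and SERPINB2 (-0.71). Others were CXCL1 (-0.82), MMP10 (-1.42), FOSL1 (-0.84), GDF15 (-0.30), CDKN1A (-0.20), MDM2 (-0.42), KRT1 (0.40) and KRT14 (-0.03). Without the 2 arrays PTGS2 stood at -1.03, IL1B at -0.96, FOS at -0.99, SERPINB2 at -0.44, CXCL1 at -0.54, MDM2 at -0.25, CDKN1A at 0.03, KRT1 at 0.11 and KRT14 at 0.10.

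Whether the dose effect in the outer slices (outside) differed from that in the 0-250 µm slice was tested on the outer mean minus that slice of each tissue. It does not set tissue beside the strip against irradiated cells alone. MMP10 was less reduced outside by 1.59 ± 0.21 and KRT19 by 0.73 ± 0.21, while SOD2 (-0.79 ± 0.23), FOSB (-1.41 ± 0.40), FOS (-0.94 ± 0.34) and PTGS2 (-1.16 ± 0.42) stood lower outside, each in 3 of 3 pairs. In limma 0 genes passed (smallest adjusted p = 0.918), 544 had an unadjusted p under 0.05, and the replicate block also gave 0. The median of all genes was -0.09 here (-0.03 without the 2 arrays). Values, medians and numbers of higher or lower genes in this paragraph are against 0, not against that median. Other values were MMP14 1.52, MMP1 0.53, LTBP2 0.78 and KRT31 0.62. Further values were BAX -1.14, COL6A3 -0.87, DLK2 -0.66, CCN1 -0.64, MT2A -0.56, PHLDA1 -0.55, AREG -0.54, SERPINB2 -0.54, SDR9C7 -0.51, MYC -0.50, TP53I3 -0.48, PPM1D -0.47, H4C8 -0.46, CDKN1A -0.30, MDM2 -0.32, IL1B -0.15, MMP3 0.43, GDF15 0.03, KRT1 0.16 and KRT14 0.00. Without the 2 arrays many of these shrank, to -0.52 for SOD2, -0.42 for FOS, -0.59 for PTGS2, -0.55 for BAX, -0.52 for COL6A3, -0.39 for CCN1, -0.25 for MT2A, -0.28 for SERPINB2 and -0.30 for MYC. Likewise LTBP2 stood at 0.39, KRT31 at 0.38, TP53I3 at -0.19, PPM1D at -0.29, H4C8 at -0.28, CDKN1A at -0.07 and MDM2 at -0.15, while IL1B turned to 0.36, KRT1 to -0.13 and KRT14 to 0.13. The metalloproteinase list was higher outside (9 of 15 genes, median 0.10, adjusted p = 0.0138; adjusted p = 0.0958 with an estimated correlation). EGFR ligands and immediate early genes were lower (21 of 26, median -0.29, adjusted p = 0.0138; adjusted p = 0.212 with an estimated correlation; 0.05 with quantile normalization). NRF2 oxidative stress genes were lower (25 of 25, median -0.27, adjusted p = 0.0282; adjusted p = 0.84 with an estimated correlation; 0.289 with quantile normalization), as were suprabasal and cornified envelope genes (26 of 30, median -0.23, adjusted p = 0.0436; adjusted p = 0.741 with an estimated correlation; 0.854 with quantile normalization).

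Along the irradiated tissue the expression of 8 genes changed with distance in limma. From 0-250 to 750-1000 µm MMP1 rose by 1.79 (adjusted p = 0.000362), the actin-binding gene MARCKSL1 by 1.67 (0.0186), MX1 by 1.49 (0.00211), MAL by 1.42 (0.0207), LGALS1 by 1.16 and the annexin ANXA3 by 1.14 (both 0.0262). With the replicate block 6 of the 8 passed, and MAL did not (adjusted p = 0.0662). These 6 genes were close to their 0-250 µm level at 500-750 µm, between -0.40 and 0.32. Of the genes that did not pass, KRT19 stood at 1.42, MMP10 at 2.18, LAMA3 at 0.96, S100A7 at 1.02 and CXCL1 at 0.42. Along the control tissue 0 genes passed in limma (133 at an unadjusted p under 0.05), with MMP1 at 0.07, SMAD7 at 1.32, MCL1 at 0.24, ZFP36 at 0.20 and ASPRV1 at 0.18. In the interaction of dose and distance 0 genes passed (194 at an unadjusted p under 0.05), MMP1 being nearest (adjusted p = 0.0907).

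For distance in irradiated tissue, 272 genes passed without the 2 arrays, 3 with median scaling and 0 with normexp. Leaving out irradiated tissue 2 gave 71 genes, irradiated tissue 1 gave 3, and control tissues 1, 2 and 3 gave 5, 1 and 1, while in control tissue leaving out control tissues 1, 2 and 3 gave 10, 44 and 1. For the interaction, 48 genes passed without the 2 arrays, 3 without control tissue 1, 17 without control tissue 2, 24 without irradiated tissue 2 and 4 without irradiated tissue 3.

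Without the 2 arrays of low quality and with replicate number as a block, a choice made after seeing the data, many more genes passed. In this model 1219 genes passed at 0-250 µm (439 higher, 780 lower), 446 at 250-500 µm (211 and 235), 417 at 500-750 µm (190 and 227) and 797 at 750-1000 µm (253 and 544). All 10, 8, 10 and 1 genes above were among them. In all 4 slices 34 genes were higher, among them CYP1B1, CYP1A1, SAA1, SAA2, CFB, the peptidoglycan-degrading amidase PGLYRP2, SOD2, SERPINA3, S100A7A and MT2A. Lower in all 4 were 70, among them MMP3, MMP9, MMP10, PLAU, IL1A, IL1B, PTGS2, FOS, MYC, DUSP6, PHLDA1 and KRT19. At 0-250 µm PGLYRP2 rose by 3.01 ± 0.08 (adjusted p = 1.73e-11), CFB at least 12.6-fold, SAA1 by 2.49, SAA2 by 2.07 and SERPINA3 by 1.66, and CEACAM6 fell by 2.78, SPINK6 by 1.62, INHBA by 1.59 and IL1B by 1.33. At 750-1000 µm 11 of 20 cell cycle and mitosis genes rose, 16 adjusted over the list alone (list adjusted p = 2.96e-24; adjusted p = 4.36e-13 with an estimated correlation), and 13 of 26 EGFR ligands and immediate early genes fell.

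With the outer mean tested in that model over all remaining arrays, 2384 genes passed, 888 higher and 1496 lower. The test on 1 value per tissue gave 0 in limma (2739 at an unadjusted p under 0.05). The model over all arrays counts the slices of a tissue as nearly independent (consensus correlation 0.112), while dose varies only between tissues. Its p-values may thus be too small, and it was not simulated without the 2 arrays and with the block. CYP1B1 rose by 3.73 ± 0.13 (adjusted p = 6.05e-10), PGLYRP2 by 2.11, SAA1 by 1.71, SERPINA3 by 1.63 and CYP1A1 by 1.55 (6.11e-05). MMP10 fell by 1.71, MMP9 by 1.47, KRT19 by 1.41, PHLDA1 by 1.37, INHBA by 1.23 and MMP1 by 1.18. Each did so in 3 of 3 pairs, as the rule by which they were named requires. PTGS2 fell by 1.03, IL1B by 1.00 and the p53 target GDF15 by 0.32 (0.00883), each in 3 of 3 pairs. CDKN1A stood at 0.04 ± 0.04 (adjusted p = 0.562). The effect outside minus that at the strip passed for 13 genes, 8 higher and 5 lower, where the test on 1 value per tissue gave 0 in limma (881 at an unadjusted p under 0.05; smallest adjusted p = 0.829). CEACAM6 (1.52), ALDH1A3 (1.29), SPINK6 (0.83) and MMP1 (0.65) were less reduced outside, and PGLYRP2 (-0.91) and SAA1 (-0.78) were less increased there. PTGS2 was lower there by a further amount (-0.60, adjusted p = 0.00333).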

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

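The tests of the 2 arrays of low quality and of handling for CYP1B1, and the 3 tests for genes that changed with distance, were chosen only after the results had been seen. So were the orders of slices within tissues, the list of aryl hydrocarbon receptor targets, the condition on its spread, and the model without the 2 arrays and with the replicate block.

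The effect of dose differed between slices for 31 genes by the interaction test in limma, without the 2 arrays and with replicate number as a block. With all 24 arrays 0 genes passed (194 at an unadjusted p under 0.05; MMP1 adjusted p = 0.0907). Differences at 0-250, 250-500, 500-750 and 750-1000 µm were -1.83, -1.71, -1.71 and -0.11 for MMP1 (interaction adjusted p = 3.94e-07), -0.71, -1.37, -1.37 and -0.15 for IFI27 (4.47e-05) and -2.13, -1.29, -1.09 and -0.12 for ALDH1A3 (0.000157). They were -1.62, -1.21, -1.18 and 0.01 for SPINK6, -2.78, -1.62, -1.90 and -0.28 for CEACAM6, and -1.94, -1.80, -1.80 and -0.62 for KRT19. Others were -1.0, -0.94, -1.01 and 0.04 for ANXA1 and -1.88, -1.52, -1.58 and -0.38 for MAL. Among the higher genes, PGLYRP2 stood at 3.01, 2.27, 2.14 and 1.90 and SAA1 at 2.49, 1.82, 1.75 and 1.55. PTGS2 moved the other way, with -0.44, -1.07, -1.02 and -1.01 (adjusted p = 0.0109).

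CYP1B1 was higher in irradiated tissue at every distance, and CYP1A1 passed at 500-750 µm. The 2 arrays of low quality are argued against as the cause. Without them the lowest CYP1B1 difference over the slices was 3.59 and it passed in each, but they belong only to 250-500 and 500-750 µm. In these slices CYP1B1 stood at 3.59 and 4.01 without them and with the replicate block (adjusted p = 2.29e-07 and 1.04e-07 in limma). At the other distances they could not have been the cause. Of 11 other listed targets of the aryl hydrocarbon receptor 9 were measured, with a median of -0.08 over the outer slices (2 higher, 7 lower), and 0.09 without the 2 arrays and with the replicate block (5 higher, 4 lower). The first met a bound of 0.1, set after the list was chosen and before it was tested, but not by more than the spread of the members, the median plus 2 standard errors being 0.19, so a broad response of these targets stays open as a hypothesis. A difference in handling or medium between irradiated and control tissues cannot be told apart from dose, since no tissue separates them and the labels name no such difference, while the finding that CYP1B1 was higher in all 4 slices on 3 of 3 scan days (lowest differences 3.14, 3.65 and 3.54) restates the pattern and decides nothing.

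In irradiated tissue 7 of the 8 genes that passed for distance, MMP1 among them, had a median 750-1000 minus 0-250 µm difference of 1.33 (1.22 to 1.41 over 3 tissues), LRRTM1, with no such difference (0.00), being left out after its values were seen. Array position is argued against as the whole cause, since in control tissue in the same positions the same genes moved by 0.04 (-0.01 to 0.09). A shift of all genes alike by scaling is argued against, since the median of all genes moved by 0 (-0.03 to 0.02) in irradiated tissue. Quantile normalization left 1.31, but with so small a shift it had little to remove and adds little. With median scaling 3 genes passed. A larger share of basal keratinocytes is argued against as the whole cause, since the 20 listed markers of that type had a median of 0.25 (0.22 to 0.28), with KRT5 at 0.05, KRT14 at 0.30 and KRT15 at 0.50 but LAMA3 at 0.96 and KRT19 at 1.42. The pattern was found and tested on the same data, and distance from the strip and handling of the slices of irradiated tissue stay open, neither tested apart from the other.

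Regrouping the 6 tissues, 3 against 3, makes 10 splits, too few for a share under 0.05, so only the real and the highest other count are given, and the real split is counted among the 10. At 0-250 µm the real split gave 10 genes and the others at most 0 (1 of 10 splits as large), at 500-750 µm 10 against 0 (1 of 10) and at 750-1000 µm 1 against 0 (1 of 10). At 250-500 µm it gave 8 and another split 83 (2 of 10 as large), and the replicate block gave 22. That other split set the dimmest arrays of the slice against the brightest. Their 75th percentiles were 190, 160 and 10.8, the last on the array of low quality, against 292, 349 and 418. Its count thus followed the signal of the arrays, and the share of the array of low quality in it was not tested. For the outer mean, the outer slices minus 0-250 µm and the interaction the real split and the highest other gave 0, so that 10 of 10 are as large by construction and nothing is decided. The lists gave 8 against 1 at 0-250 µm (1 of 10) and 6 against 4 for the outer mean (1 of 10). For the outer mean further splits gave 1, 2 or 3 lists, so the preset correlation also called lists where the doses were mixed. The real split parts all 3 same-day pairs, as do 3 others, while the remaining 6 part 1 pair each. Against the splits that part all pairs, the replicate block without the 2 arrays gave 1219 against 0, 446 against 2, 417 against 0 and 797 against 0 from the nearest to the farthest slice. It gave 2384 against 6 for the outer mean over all arrays, 13 against 0 for outer minus 0-250 µm and 31 against 2 for the interaction. These are 4 splits, again too few for a share under 0.05. The others swap the doses of 1 pair, which puts the dose difference into their residual spread and can lower their counts. The model was also picked under the real labels, so these counts decide nothing. Of 100 groupings of 12 arrays into 4 groups of 3, the real included, 3 gave as many genes as distance in irradiated tissue (8 genes; highest other 14). These mix tissues, so distance was also shuffled within each tissue, where 2 of 100 orders, the real included, gave as many (highest other 12). That share lies under 0.05 for the count from all arrays. The orders were drawn, and the slide correlation was held at its value for the real order, so a chance order is made unlikely but not excluded. Without replicate numbers 1 and 3 that count was 1 and 0. In control tissue the count was 0 (highest other 0), so that all 100 regroupings are as large by construction and nothing is decided.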

How the results depend on the processing

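The models without the 2 arrays of low quality, the floor of 0.1 and the outer slices tested over the remaining arrays were chosen only after the results had been seen. The 246 results for single genes were recomputed under each alternative that could give them, 5744 values in all. None that passed in either setting changed direction (0), 289 lost their call, 331 gained one and 5124 stayed on their side of the threshold. Of these last, 160 passed in neither setting and changed sign. CYP1B1 kept its call in 22 of 23 settings at 0-250 µm (1.90 to 4.64), 21 of 23 at 250-500 µm (0.84 to 3.89). It kept its call in 21 of 23 at 500-750 µm (1.58 to 4.26) and 22 of 23 at 750-1000 µm (2.01 to 3.73). MMP1 kept it in 17 of 23 at 0-250 µm, 19 of 23 at 250-500 µm and 16 of 23 at 500-750 µm. Every alternative planned for a count of called genes gave a value. For most single-gene results the filter on all 24 arrays gave none, CYP1B1 in each slice among them. Under it 85 stayed on their side of the threshold and 1 lost its call. Except where the alternative held fewer arrays or genes, the cause was not tested. Signal over background limited the tests to 22565 of 41000 probes. Of the 17421 genes tested, 5508 had their probe well above background on all arrays.

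Counts of called genes in limma moved by more than 1.5 times as follows. At 0-250 µm the 10 genes became 29 at an unadjusted p of 0.001, 5 with median scaling, 0 with normexp and 0 with the filter on all 24 arrays. They became 82 with array weights, 6 with the 6 arrays alone, 38 without the 2 arrays and 1219 without them and with the replicate block. At 250-500 µm the 8 genes became 41 at an unadjusted p of 0.001, 18 with quantile normalization, 0 with normexp, 15 with the floor of 0.1, 14 with the series matrix, 19 with no filter and 2 with the filter on all 24 arrays. They became 71 with array weights, 15 with no slide block, 0 with the 6 arrays alone, 34 without the 2 arrays and 446 with the block as well. At 500-750 µm the 10 genes became 41 at an unadjusted p of 0.001, 0 with normexp, 18 with the series matrix, 29 with no filter and 0 with the filter on all 24 arrays. Array weights gave 69, the 6 arrays alone 0, leaving out the 2 arrays 34 and doing so with the block 417. At 750-1000 µm the 1 gene became 8 at an unadjusted p of 0.001, 0 with normexp, 2 with the series matrix and 0 with the filter on all 24 arrays. It became 52 with array weights, 8 without the 2 arrays and 797 with the block as well.

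For the mean of the outer slices the 0 genes became 12 at an unadjusted p of 0.001, 1 with the floor of 0.1, 1 with the series matrix, 22 in the model of all 24 arrays and 2384 in that model without the 2 arrays and with the block. For outer minus 0-250 µm the 0 genes became 3 at an unadjusted p of 0.001 and 13 in the last of these models. The 0 genes of the interaction became 11 at an unadjusted p of 0.001, 1 with quantile normalization, 2 with the series matrix and 2 with no filter. They became 120 with array weights, 48 without the 2 arrays and 31 with the block as well. For distance in control tissue 0 genes became 2 at an unadjusted p of 0.001, 2 with no filter, 4 with array weights, 1 without the 2 arrays and 1 with the block as well. For distance in irradiated tissue 8 genes became 27 at an unadjusted p of 0.001, 3 with median scaling, 0 with normexp, 14 with the series matrix, 14 with no filter and 0 with the filter on all 24 arrays. The count was 983 with array weights, 2 with no slide block, 272 without the 2 arrays and 202 with the block as well. The lists called at 0-250 µm went from 8 to 2 with an estimated correlation. The lists called for the outer mean went from 6 to 2 with an estimated correlation, 14 with normexp, 10 with no filter, 10 with array weights, 10 without the 2 arrays and 12 over all remaining arrays with the block.

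The replicate block, for which the numbers pair the samples, gave 22 genes at 250-500 µm, 19 at 500-750 µm and 1 for the outer mean. It gave 13 at 0-250 µm, 1 at 750-1000 µm, 0 for outer minus 0-250 µm, the interaction and distance in control tissue, 6 for distance in irradiated tissue, and 8 and 6 lists. No other count moved by more than 1.5 times.

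Leaving out 1 tissue or 1 replicate number gave 1 to 31 genes at 0-250 µm, 2 to 19 at 250-500 µm, 1 to 32 at 500-750 µm, 1 to 9 at 750-1000 µm, 0 to 0 for the outer mean and 0 to 0 for outer minus 0-250 µm. The range was 0 to 25 for the interaction, 0 to 44 for distance in control tissue and 0 to 71 for distance in irradiated tissue, with 5 to 9 lists at 0-250 µm and 5 to 7 for the outer mean. Without replicate numbers 1, 2 and 3 the counts were 4, 30 and 1 at 0-250 µm, and 2, 9 and 2 at 250-500 µm. They were 2, 32 and 1 at 500-750 µm, and 1, 22 and 0 for distance in irradiated tissue. Without replicate number 2 there were 3 genes at 750-1000 µm, 25 for the interaction and 42 for distance in control tissue, where number 1 left 4. Control tissue 2 left 5 lists at 0-250 µm.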

Other observations

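The tests of lists without the 2 arrays of low quality were chosen only after the results had been seen.

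Lists that were not called in the mean of the outer slices are given here with the median log2 difference of their measured genes and the adjusted p of cameraPR. The median of all genes was -0.09 here (-0.03 without the 2 arrays), so a list near it was not shifted against the other genes. Among lists of stress and signalling, p53 targets stood at -0.22 (6 of 28 higher; 0.296), DNA repair at -0.14 (0.954), and DNA replication at 0.03 (0.388). Inflammatory cytokines and chemokines stood at -0.08 (0.24), NF-kappaB feedback and prostaglandin genes at -0.07 (0.388), and interferon response at -0.08 (0.536). NRF2 oxidative stress genes stood at -0.04 (0.952), heat shock and unfolded protein at -0.18 (0.477), hypoxia and glycolysis at -0.24 (0.215), TGF-beta and wound matrix at -0.11 (0.536) and apoptosis regulators at -0.08 (0.66). Among lists of tissue structure, suprabasal and cornified envelope stood at -0.10 (0.844), lipid barrier and ceramide genes at -0.22 (0.338), antimicrobial and S100 at -0.19 (0.883) and gap junction and connexin at -0.28 (2 of 14 higher; 0.388). Oxidative phosphorylation stood at -0.23 (0.112), ribosomal proteins at -0.14 (0.509) and replication-dependent histones at -0.18 (0.296). Markers of other cell types stood at 0.29 for melanocytes (7 measured; 0.388), -0.09 for fibroblasts (8; 0.8), 0.14 for immune and endothelial cells (8; 0.388) and 0.11 for sweat, sebaceous and hair follicle cells (12; 0.416).

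Without the 2 arrays and with replicate number as a block, cell cycle and mitosis genes moved up in every slice, with medians of 0.21 at 0-250 µm, 0.20 at 250-500 µm, 0.35 at 500-750 µm and 0.61 at 750-1000 µm, and adjusted p of 0.0218, 9.07e-05, 1.71e-06 and 2.96e-24. At 0-250 µm the adjusted p was 0.168 with an estimated correlation. In the outer slices minus 0-250 µm the list was higher, with a median of 0.29, 16 of 20 genes higher and adjusted p = 4.95e-06, while 0 of its genes passed singly. In the same model 3 of 29 DNA repair genes rose at 750-1000 µm, FANCA (1.26), FANCG (0.49) and RAD54L (0.50).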
